A study of Homo sapiens with 25 samples.

How the data were processed

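The series holds RNA-seq and ChIP-seq of THP-1 cells treated for 48 h with 30, 50 or 100 µM IOX1 or with the DMSO vehicle, at 0.1% vehicle. The 12 RNA libraries fall into 4 groups of 3. ChIP-seq has 1 peak list for each of H3K9me2, H3K9me3 and H3K27me3 in each treatment, and an untreated input library is not analysed here. Nothing in the labels says that the 3 RNA libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The 12 pairs of libraries within groups all differed by more than sampling noise (lowest chi-square per degree of freedom 8.49), and each library was counted as 1 replicate.

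The RNA file holds raw counts per Ensembl gene as deposited, for 58884 genes, with no normalization. Per the submitters' processing notes, tools named for the series are Trim Galore, FastQC 0.11.8, HISAT2, SAMtools 0.1.19, featureCounts, Subread 1.6.4, BWA, Picard and MACS2, with the build GRCh38. Per the labels' protocols, the RNA libraries were made with a stranded poly(A) kit. The strand setting of the counting and the annotation release are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. The ChIP files are broad peak lists with a fold enrichment (a ratio) and a -log10 p and -log10 q for each peak, as deposited by the authors. The caller's cutoffs, its control and the ChIP depth are not given in the sources used here. The lowest -log10 q of any peak was 1.00.

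Gene symbols came from the reference gene name table, which matched 58472 of the IDs and left 412 without one. Differential expression was computed with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 4 groups, which kept 16937 genes, TMM factors, and a quasi-likelihood fit with group as its only term. All 12 libraries entered 1 fit and shared an estimate of the spread (common biological coefficient of variation 0.131). Each dose was compared with DMSO and with each other dose, and a joint test covered any difference among the groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and counts are also given for a log2 fold change of at least 1 either way. CPM values are means with the SD of 3 libraries. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts it is a ratio with an exact counting interval. Intervals and floors cover counting error only.

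The gene lists, the planned tests and alternatives and the rule for named genes were fixed before the data were examined, and tests and settings chosen later are named as such where they are given. There were 37 lists, of which 35 had at least 3 tested members. Each was tested against the other genes with camera of limma 3.58.1 on voom values, with the inter-gene correlation preset at 0.01, Benjamini-Hochberg adjustment over 105 tests, and an estimated correlation beside it. Of 44 calls with the preset correlation, 4 held with the estimated correlation. Per dose against DMSO the rule named the 6 highest and 6 lowest log2 fold changes among called protein-coding genes with a mean log2 CPM of at least 1 and no overlap between treated and DMSO libraries. It also took the 3 highest and 3 lowest per pair of doses, up to 4 members of each list with the smallest p among those called, and the KDM4 genes whatever their values. Overlaps of calls between doses share the DMSO libraries. The overlap of independent lists and 20 simulations of unchanged groups are given beside them. Each simulation drew all 12 libraries anew, DMSO included, with no gene changed. With no changed genes few calls can be shared, so they cannot show how much the shared DMSO libraries add to overlaps of real calls.

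Peaks were used as listed on chromosomes 1-22, X and Y, with bedtools 2.31.1, Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1. Overlap means at least 1 bp, and shares carry exact Clopper-Pearson 95% intervals, which cover the number of peaks and no replicate error. The fold of a peak is the authors' value, and its scale may differ between lists. It was used within its list, except for the cutoff of at least 3 and the range given at PGK1. Named regions were, per mark, the 2 DMSO peaks of highest fold, the 2 widest, and, of those overlapped in all 3 treated lists, the 2 of highest fold at 100 µM. The plan had been to join peaks to genes at transcription start sites. The gene table used here has no strand, so a gene was joined to any DMSO peak from 1 kb before to 1 kb after its span in RefSeq GRCh38, found for 15559 of the tested genes (91.9%). These sets were tested with camera over 9 tests.

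The fits were tested on counts simulated for 16937 genes from the DMSO means and the library sizes of the real samples. In each comparison 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale, either way. Far more genes were called in the real comparisons, so the rates below need not hold there. For the simulated 30, 50 and 100 µM comparisons, edgeR recovered 95.5%, 91.0% and 83.6% of genes changed by 1 on the log2 scale. For a change of 0.5 it recovered 22.4%, 19.4% and 22.4%. False calls made up 6.45%, 4.79% and 2.84% of its calls. For DESeq2 1.42.0 they made up 13.2%, 18.4% and 13.2%. With the preset correlation, camera found a simulated set of 30 genes changed at 100 µM. It called 0 of 62 unchanged tests over the simulated 30, 50 and 100 µM comparisons. Genes were simulated independently, so this does not test whether the preset correlation is high enough. In the real lists the estimated correlation reached 0.79, for cytosolic ribosomal proteins. Alternatives were RLE and upper-quartile factors, DESeq2, limma-voom, no filter, a filter of CPM at least 1 in 3 libraries, a replicate block, only the 6 libraries compared, and each library of a comparison left out in turn (for overlaps between doses, each of the 12). For peaks they were a -log10 q of at least 3, a fold of at least 3, merging within 5 kb and overlap over 0.5 of the peak. Figures were drawn with matplotlib 3.10.9.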

Results

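RNA and histone methylation were measured in THP-1, a human acute monocytic leukaemia cell line, after 48 h with IOX1, an inhibitor of 2-oxoglutarate oxygenases, in a study of KDM4A inhibition. RNA was sequenced in 3 libraries for each of DMSO and 30, 50 and 100 µM IOX1. H3K9me2, H3K9me3 and H3K27me3 were mapped by ChIP-seq, with 1 peak list for each mark and treatment and no replicate. The RNA libraries held 38.3 ± 3.94 M counts (M, 1e6) in DMSO, 43.9 ± 5.36 at 30 µM, 35.1 ± 2.07 at 50 µM and 36.6 ± 14.0 at 100 µM (SD, n = 3 each), from 27.3 to 52.7 M over all 12. The 100 µM libraries stood apart on the first principal component, which carried 77.1% of the variance. In them the mitochondrial ribosomal RNA MT-RNR2 took 4.12 ± 0.257% of the counts, against 0.166 ± 0.0211% in DMSO (SD, n = 3 each). Log2 fold changes below are IOX1 over DMSO unless stated, with their standard error, from 3 libraries per group.

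The KDM4 genes, which encode histone demethylases that IOX1 inhibits, were followed first, to see whether their own RNA changed. KDM4A (chromosome 1, 43650149 to 43705518, GRCh38) stood at 85.8 ± 4.10 CPM in DMSO and 55.3 ± 5.42 CPM at 100 µM (SD, n = 3). It fell by 0.64 ± 0.092 on the log2 scale at 100 µM (edgeR adjusted p = 1.83e-05). At 30 and 50 µM its log2 fold changes of -0.09 ± 0.091 and 0.03 ± 0.091 did not pass the edgeR test (adjusted p = 0.568 and 0.784). KDM4B and KDM4C rose at 100 µM, by 1.44 ± 0.132 and 1.79 ± 0.085 (edgeR adjusted p = 1.39e-07 and 9.23e-11). KDM4C was also higher at 30 µM, by 0.41 ± 0.083, and at 50 µM, by 0.43 ± 0.083. KDM4B, at 0.29 ± 0.13 at 50 µM, missed the threshold (edgeR adjusted p = 0.0735) but passed it with only the 6 libraries compared (adjusted p = 0.0132) and with no filter (adjusted p = 0.0497). KDM4D passed at 50 µM, with 0.69 ± 0.25 (edgeR adjusted p = 0.0324). That call was lost without DMSO replicate 2 or 3 (adjusted p = 0.0610 and 0.120) and without 50 µM replicate 1 or 2 (adjusted p = 0.0775 and 0.141). It was also lost with DESeq2 (adjusted p = 0.0667) and with no filter in edgeR (adjusted p = 0.0713). KDM4E had too few counts to be tested.

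**Figure D1:**
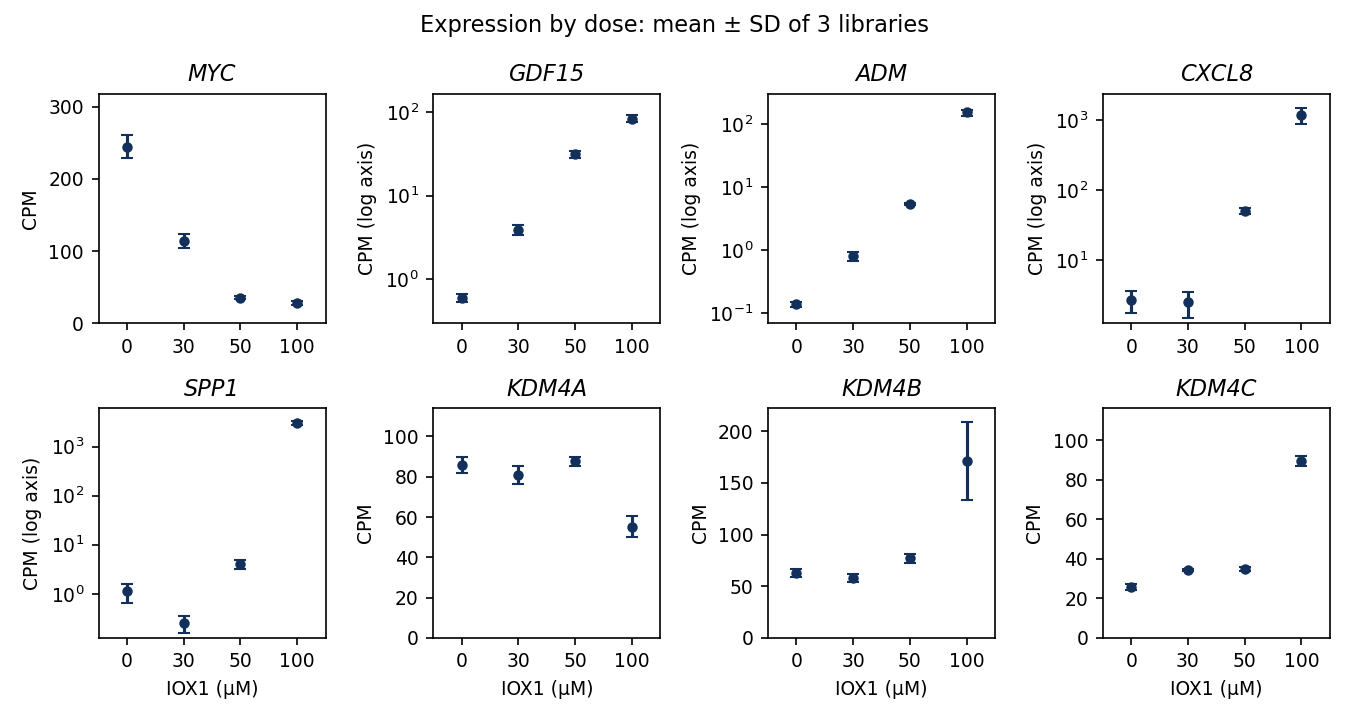
Mean CPM of 8 genes with the SD of 3 libraries (bars) at 0 (DMSO), 30, 50 and 100 µM IOX1, on a linear axis from 0 or a log axis as labelled. Between DMSO and 100 µM MYC went from 245 to 28.2 CPM and SPP1 from 1.13 to 3050 CPM, and KDM4A was lower at 100 µM than in DMSO.

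The comparison of 30 µM with DMSO asked what the lowest dose changed. Most NRF2 targets were higher, and 15 of 30 MYC-linked ribosome biogenesis genes, MYC among them, were lower. OSGIN1, an oxidative stress response gene, rose by 2.99 ± 0.221 on the log2 scale and GDF15, a stress-induced cytokine gene, by 2.71 ± 0.167. ADM, which encodes adrenomedullin, rose by 2.54 ± 0.242, NGFR by 2.82 ± 0.479 and FAM167A by 2.67 ± 0.507. Genes that fell included PNCK (-3.95 ± 0.404), TNFRSF19 (-3.25 ± 0.254), KLHL4 (-2.76 ± 0.262), CNR1 (-2.60 ± 0.253) and the interleukin-7 receptor gene IL7R (-2.59 ± 0.298). IL1A had 0 counts in DMSO and 6 at 30 µM, at least 1.80-fold higher. Its call was lost without DMSO replicate 1, 2 or 3 (edgeR adjusted p = 0.103, 0.0918 and 0.0920) and without 30 µM replicate 1 or 3 (adjusted p = 0.0671 and 0.0944). It was also lost with DESeq2 (adjusted p = 0.0608) and, by a narrow margin, with no filter in edgeR (adjusted p = 0.05001).

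Of 26 NRF2 targets, 16 were higher and 3 lower (17 and 3 adjusted over the list alone) at 30 µM. NRF2 targets passed the set test (camera adjusted p = 2.98e-09, and adjusted p = 0.114 with an estimated correlation), with NQO1 at 1.90 ± 0.106 and GSR at 1.07 ± 0.083. Of 30 MYC-linked ribosome biogenesis genes, 0 were higher and 15 lower (0 and 21 adjusted over the list alone), including MYC at -1.10 ± 0.101 and WDR43 at -0.64 ± 0.094 (camera adjusted p = 1.77e-10, and adjusted p = 0.103 with an estimated correlation). Of 34 G2/M and mitosis genes, 1 was higher and 13 lower (2 and 18 adjusted over the list alone), with CCNB1, which encodes cyclin B1, at -0.54 ± 0.087 (camera adjusted p = 3.15e-07, and adjusted p = 0.0680 with an estimated correlation). Of 36 genes of the amino acid stress response, 2 were higher and 17 lower (4 and 17 adjusted over the list alone) (camera adjusted p = 1.81e-05, and adjusted p = 0.240 with an estimated correlation). Among those called, CHAC1 stood at -1.55 ± 0.157, while GDF15, named above, rose by 2.71. Of 31 monocyte and macrophage genes, 14 were higher and 5 lower (15 and 7 adjusted over the list alone), and S100A8 rose by 1.84 ± 0.14 (camera adjusted p = 0.00746, and adjusted p = 0.139 with an estimated correlation). Of 24 autophagy and lysosome genes, 12 were higher and 2 lower (13 and 3 adjusted over the list alone), with WIPI1 at 1.35 ± 0.105 (camera adjusted p = 5.40e-04, and adjusted p = 0.173 with an estimated correlation). Of 23 p53 targets, 5 were higher and 0 lower (5 and 0 adjusted over the list alone), with the cell cycle inhibitor gene CDKN1A at 1.48 ± 0.101 (camera adjusted p = 0.00213, and adjusted p = 0.0544 with an estimated correlation).

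Of 38 interferon-stimulated genes, 12 were higher and 1 lower (14 and 1 adjusted over the list alone) at 30 µM, with IFIT2 at 0.93 ± 0.122 (camera adjusted p = 0.00746, and adjusted p = 0.103 with an estimated correlation). Of 20 immediate-early and heat shock genes, 9 were higher and 0 lower (11 and 2 adjusted over the list alone), with FOS at 1.73 ± 0.131 (camera adjusted p = 0.00945, and adjusted p = 0.294 with an estimated correlation). Of 9 metallothioneins and metal response genes, 0 were higher and 5 lower (1 and 5 adjusted over the list alone), with MT1G at -1.58 ± 0.14 (camera adjusted p = 6.00e-04, and adjusted p = 0.0546 with an estimated correlation). Of 40 hypoxia targets, 7 were higher and 14 lower (8 and 15 adjusted over the list alone) (camera adjusted p = 0.0390, and adjusted p = 0.582 with an estimated correlation). Among those called, AK4 stood at -1.44 ± 0.155 and BNIP3 at -1.05 ± 0.156, while ADM, named above, rose by 2.54. The hypoxia call was lost without DMSO replicate 2 (adjusted p = 0.149) and without 30 µM replicate 1 or 3 (adjusted p = 0.0756 and 0.0667). Of 24 inflammatory cytokine and NF-kB genes, 9 were higher and 2 lower (11 and 2 adjusted over the list alone), with TNFAIP2 at 1.01 ± 0.097 (camera adjusted p = 0.0259, and adjusted p = 0.294 with an estimated correlation). Without DMSO replicate 3 this call was lost (adjusted p = 0.0609).

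Over all 16937 genes tested at 30 µM, 2015 were higher and 1335 lower, of which 273 and 436 changed by at least 1 on the log2 scale. Leaving out DMSO replicate 1, DMSO replicate 2 or 30 µM replicate 2 gave 840, 837 or 854 lower genes, and fitting only the 6 libraries compared gave 2285. With the stricter filter, 267 genes were lower by at least 1.

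The 50 µM comparison asked what a middle dose changed. Inflammatory and interferon genes were higher together, and the ribosome biogenesis list was lower throughout. Of 24 inflammatory cytokine and NF-kB genes, 20 were higher and 0 lower (21 and 0 adjusted over the list alone) (camera adjusted p = 1.09e-11, and adjusted p = 0.0416 with an estimated correlation). They included the adhesion gene ICAM1 at 3.75 ± 0.139, TNFAIP3 at 2.54 ± 0.095 and the cytokine gene IL1B at 3.09 ± 0.15. Of 38 interferon-stimulated genes, 32 were higher and 1 lower (34 and 1 adjusted over the list alone), with OAS3 at 2.70 ± 0.132 and IRF7 at 1.78 ± 0.123 (camera adjusted p = 4.46e-10, and adjusted p = 0.0199 with an estimated correlation). Of 30 MYC-linked ribosome biogenesis genes, 0 were higher and 30 lower (0 and 30 adjusted over the list alone), with MYC at -2.78 ± 0.107 and NOP16 at -1.92 ± 0.11 (camera adjusted p = 3.40e-17, and adjusted p = 0.0544 with an estimated correlation).

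Of 26 NRF2 targets, 19 were higher and 0 lower (19 and 1 adjusted over the list alone) at 50 µM, and HMOX1, the haem oxygenase gene, rose by 4.85 ± 0.141 (camera adjusted p = 1.09e-07, and adjusted p = 0.152 with an estimated correlation). Of 40 hypoxia targets, 23 were higher and 2 lower (23 and 2 adjusted over the list alone), with NDRG1 at 2.46 ± 0.088 and the glucose transporter gene SLC2A3 at 3.09 ± 0.142 (camera adjusted p = 5.07e-06, and adjusted p = 0.173 with an estimated correlation). Of 31 monocyte and macrophage genes, 21 were higher and 2 lower (21 and 2 adjusted over the list alone), with the integrin gene ITGAM at 2.63 ± 0.094 (camera adjusted p = 3.19e-06, and adjusted p = 0.0544 with an estimated correlation). Of 23 p53 targets, 11 were higher and 1 lower (11 and 1 adjusted over the list alone), with CDKN1A at 2.92 ± 0.106 (camera adjusted p = 0.00195, and adjusted p = 0.0544 with an estimated correlation). Of 24 autophagy and lysosome genes, 17 were higher and 2 lower (17 and 3 adjusted over the list alone), with SQSTM1 at 2.74 ± 0.124 (camera adjusted p = 3.77e-05, and adjusted p = 0.114 with an estimated correlation). Of 34 G2/M and mitosis genes, 1 was higher and 22 lower (1 and 22 adjusted over the list alone), with BUB1 at -1.17 ± 0.089 (camera adjusted p = 2.43e-06, and adjusted p = 0.0911 with an estimated correlation). Of 20 immediate-early and heat shock genes, 13 were higher and 5 lower (14 and 5 adjusted over the list alone), with JUN at 4.15 ± 0.195 (camera adjusted p = 0.00746, and adjusted p = 0.284 with an estimated correlation). Of 18 BCL2 family genes, which act for or against cell death, 11 were higher and 2 lower (12 and 3 adjusted over the list alone), with BCL2A1 at 2.96 ± 0.163 and BCL2 at -0.88 ± 0.109, both known to protect cells (camera adjusted p = 0.0217, and adjusted p = 0.393 with an estimated correlation).

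Among single genes at 50 µM, NGFR rose by 6.50 ± 0.334, GDF15 by 5.70 ± 0.163, ADM by 5.26 ± 0.194 and FAM167A by 5.13 ± 0.388. IER3, an immediate-early gene, had 3 counts in DMSO and 339 at 50 µM, a ratio of 131 with a counting interval of 44.3 to 636. IL1A had 0 and 24 counts, at least 9.24-fold higher. The lowest were TNFRSF19 (-6.58 ± 0.37), SERPINB2 (-6.44 ± 0.263), CYP2W1 (-6.27 ± 0.314), the telomerase gene TERT (-5.10 ± 0.312), ROS1 (-4.46 ± 0.225) and SERPINB10 (-4.09 ± 0.207). In all, 4600 genes were higher and 4143 lower, with 1850 and 1542 changed by at least 1 on the log2 scale. The mitochondrial ribosomal RNA MT-RNR2 was also higher at 50 µM, by 1.36 ± 0.113 (edgeR adjusted p = 2.71e-07), at 0.403 ± 0.0211% of the counts (SD, n = 3).

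The 100 µM comparison asked what the highest dose changed. The cell cycle lists were lower in full, and hypoxia and inflammatory genes were higher. Of 34 G2/M and mitosis genes, 0 were higher and 34 lower (0 and 34 adjusted over the list alone), with the topoisomerase gene TOP2A at -4.57 ± 0.147 and CCNB1 at -2.98 ± 0.095 (camera adjusted p = 1.35e-14, and adjusted p = 0.0416 with an estimated correlation). Of 38 DNA replication and G1/S genes, 0 were higher and 38 lower (0 and 38 adjusted over the list alone), with the helicase subunit gene MCM6 at -3.56 ± 0.082 and MCM10 at -5.46 ± 0.151 (camera adjusted p = 8.77e-15, and adjusted p = 0.0544 with an estimated correlation). Of 26 homologous recombination and Fanconi genes, 0 were higher and 26 lower (0 and 26 adjusted over the list alone) (camera adjusted p = 1.08e-09, and adjusted p = 0.103 with an estimated correlation). Of 40 hypoxia targets, 39 were higher and 1 lower (39 and 1 adjusted over the list alone), with ADM at 10.07 ± 0.184 and NDRG1 at 6.21 ± 0.104 (camera adjusted p = 2.91e-14, and adjusted p = 0.0544 with an estimated correlation). Of 24 inflammatory cytokine and NF-kB genes, 24 were higher and 0 lower (24 and 0 adjusted over the list alone), with IL1B at 7.34 ± 0.156 (camera adjusted p = 1.77e-10, and adjusted p = 0.0416 with an estimated correlation). In these libraries MT-RNR2 stood at 5.18 ± 0.133 on the log2 scale.

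**Figure D2:**
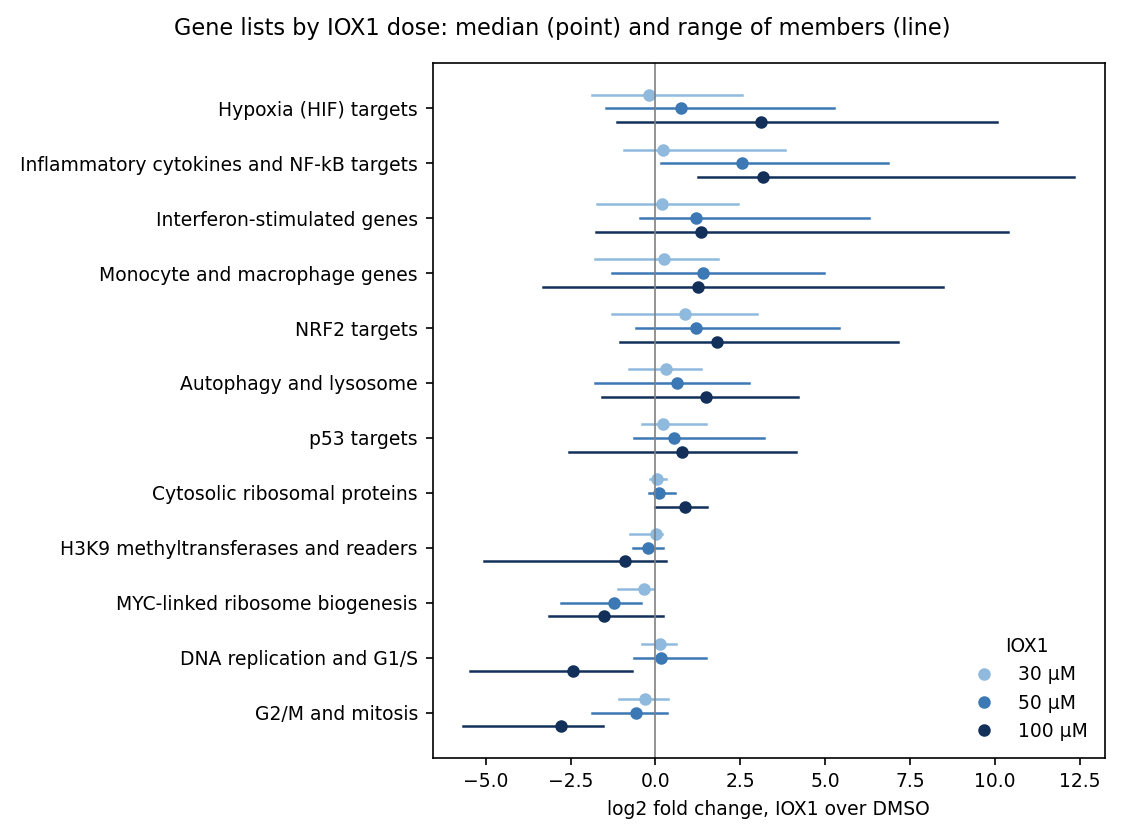
Median log2 fold change (points) and range of tested members (lines) of 12 gene lists at 30, 50 and 100 µM IOX1, each against DMSO. Range ends set by genes with 0 counts in DMSO, such as IL1A, depend on the prior count of the fit; the hypoxia median went from -0.19 to 0.77 and 3.10, and that of DNA replication from 0.14 and 0.17 to -2.43.

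Of 20 glycolysis genes, 16 were higher and 4 lower (16 and 4 adjusted over the list alone) at 100 µM, with the hexokinase gene HK2 at 3.91 ± 0.087 and ENO2 at 7.71 ± 0.178 (camera adjusted p = 1.70e-04, and adjusted p = 0.361 with an estimated correlation). Of 26 NRF2 targets, 23 were higher and 3 lower (23 and 3 adjusted over the list alone), with HMOX1 at 7.16 ± 0.146 (camera adjusted p = 2.12e-06, and adjusted p = 0.188 with an estimated correlation). Of 24 autophagy and lysosome genes, 18 were higher and 1 lower (18 and 1 adjusted over the list alone), with the cathepsin gene CTSB at 3.52 ± 0.088 (camera adjusted p = 3.58e-06, and adjusted p = 0.103 with an estimated correlation). Of 38 interferon-stimulated genes, 23 were higher and 10 lower (23 and 10 adjusted over the list alone), with IFI6 at 3.82 ± 0.144 (camera adjusted p = 0.00865, and adjusted p = 0.103 with an estimated correlation). Of 31 monocyte and macrophage genes, 19 were higher and 9 lower (19 and 9 adjusted over the list alone), with CD86 at 6.75 ± 0.13 (camera adjusted p = 0.0221, and adjusted p = 0.188 with an estimated correlation). Of 20 immediate-early and heat shock genes, 13 were higher and 3 lower (13 and 3 adjusted over the list alone), with JUN at 6.54 ± 0.214 (camera adjusted p = 0.00167, and adjusted p = 0.227 with an estimated correlation). Of 21 ER chaperone genes, 14 were higher and 4 lower (14 and 4 adjusted over the list alone), with HSPA5 at 2.26 ± 0.086 (camera adjusted p = 0.00710, and adjusted p = 0.240 with an estimated correlation).

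Of 30 MYC-linked ribosome biogenesis genes, 1 was higher and 27 lower (1 and 27 adjusted over the list alone) at 100 µM, with MYC at -3.12 ± 0.11 (camera adjusted p = 9.31e-09, and adjusted p = 0.136 with an estimated correlation). Cytosolic ribosomal protein genes moved the other way, with a median of 0.86. Of these 54, 52 were higher and 0 lower (52 and 0 adjusted over the list alone) (camera adjusted p = 1.53e-08, and adjusted p = 0.582 with an estimated correlation). Of 40 nuclear oxidative phosphorylation genes, 2 were higher and 23 lower (2 and 23 adjusted over the list alone), with ATP5MC1 at -2.06 ± 0.138 (camera adjusted p = 0.0168, and adjusted p = 0.665 with an estimated correlation). Of 18 H3K9 methyltransferases and readers, 2 were higher and 13 lower (2 and 14 adjusted over the list alone), with UHRF1 at -5.06 ± 0.199 and the heterochromatin protein gene CBX5 at -3.31 ± 0.129 (camera adjusted p = 0.00190, and adjusted p = 0.103 with an estimated correlation). Of 18 BCL2 family genes, 12 were higher and 3 lower (12 and 3 adjusted over the list alone), with BCL2 at -3.37 ± 0.123 and the death-promoting BMF at 3.37 ± 0.128 (camera adjusted p = 0.0259, and adjusted p = 0.405 with an estimated correlation).

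Several of the highest genes at 100 µM had no counts in DMSO. TFPI2, a protease inhibitor gene, went from 0 to 3280 counts, at least 1689-fold higher. IL1A was at least 731-fold, the integrin gene ITGB8 at least 562-fold and CHST15 at least 400.2-fold higher. RGS1 had 3 counts in DMSO, with a ratio of 3681 (counting interval 1259 to 17855). SPP1, which encodes osteopontin, went from 1.13 ± 0.467 CPM to 3050 ± 284 CPM, a log2 fold change of 11.38 ± 0.28. The lowest were SERPINB10 (-7.88 ± 0.309), VIT (-7.87 ± 0.193), CYP2W1 (-7.54 ± 0.382), TEX15 (-7.36 ± 0.334), the helicase gene PIF1 (-7.06 ± 0.309) and WDR49 (-7.00 ± 0.203). In all, 6314 genes were higher and 6657 lower, of which 3995 and 4467 changed by at least 1 on the log2 scale. These calls made up 76.6% of the tested genes, while TMM scaling takes most genes as unchanged. The balance of higher and lower genes, and shifts common to many genes of a list, are therefore relative to the scaling. With no scaling factors, log2 fold changes at 100 µM shifted by -0.55.

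The doses were compared with each other to ask how the response differed between them. From 30 to 50 µM the chemokine gene CXCL8 rose by 4.32 ± 0.274, IER3 by 4.64 ± 0.291 and SLAMF7 by 4.29 ± 0.406. Over the same step CYP2W1 fell by 4.61 ± 0.328, SERPINB2 by 3.88 ± 0.325 and TNFRSF19 by 3.34 ± 0.455. From 50 to 100 µM SPP1 rose by 9.54 ± 0.256, and TFPI2 and ITGB8 went from 1 and 3 counts to 3280 and 1091. PYHIN1 fell by 6.21 ± 0.406, the meiotic gene DMC1 by 5.70 ± 0.313 and WDR49 by 5.49 ± 0.222. From 30 to 100 µM SPP1 rose by 13.59 ± 0.316, TFPI2 went from 0 to 3280 counts and GEM from 3 to 2164. TEX15 fell by 7.17 ± 0.336, VIT by 6.86 ± 0.196 and WDR49 by 6.40 ± 0.209. Calls were 2916 higher and 2530 lower for 50 against 30 µM, 5671 and 5940 for 100 against 50 µM, and 6046 and 6540 for 100 against 30 µM. Both steps raised 1619 genes and lowered 1362, and the joint test called 14124.

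Calls at different doses overlapped. Of the genes higher at 30 µM, 1861 were also higher at 50 µM, where independent lists would share 547 and simulated unchanged groups shared 0. For lower genes the overlap was 1128, against 327 for independent lists and at most 1 in any of the simulations. Without DMSO replicate 1, DMSO replicate 2 or 30 µM replicate 2 it was 694, 692 or 713. Between 30 and 100 µM, 1444 higher genes were shared against 751, and 977 lower genes against 525. The lower overlap was 627, 617 or 631 without those libraries. Between 50 and 100 µM, 3294 higher and 3269 lower genes were shared, against 1715 and 1628; simulated unchanged groups shared 0 in either pair with 100 µM. Part of each overlap may come from the shared DMSO libraries. How much was not measured, since the simulations held no changed genes.

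The ChIP-seq lists were compared to ask whether regions of histone methylation differed after IOX1. The H3K27me3 list went from 58131 peaks in DMSO to 1750 at 30 µM, 346 at 50 µM and 206 at 100 µM. H3K9me2 went from 3488 peaks to 109, 31 and 498, and H3K9me3 from 2234 to 4999, 550 and 334. Covered length for H3K27me3 went from 21762 kb to 389.7, 73.6 and 37.4 kb. For H3K9me2 it went from 552 kb to 27.1, 6.31 and 100.4 kb, and for H3K9me3 from 754 kb to 1274, 214 and 103 kb. With peaks of -log10 q of at least 3 the H3K9me3 list at 30 µM was the shorter, at 574 peaks against 680 in DMSO, which turns the direction of that difference. The lists have no replicates and the depth behind them is unknown, so no difference between them was tested.

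**Figure D3:**
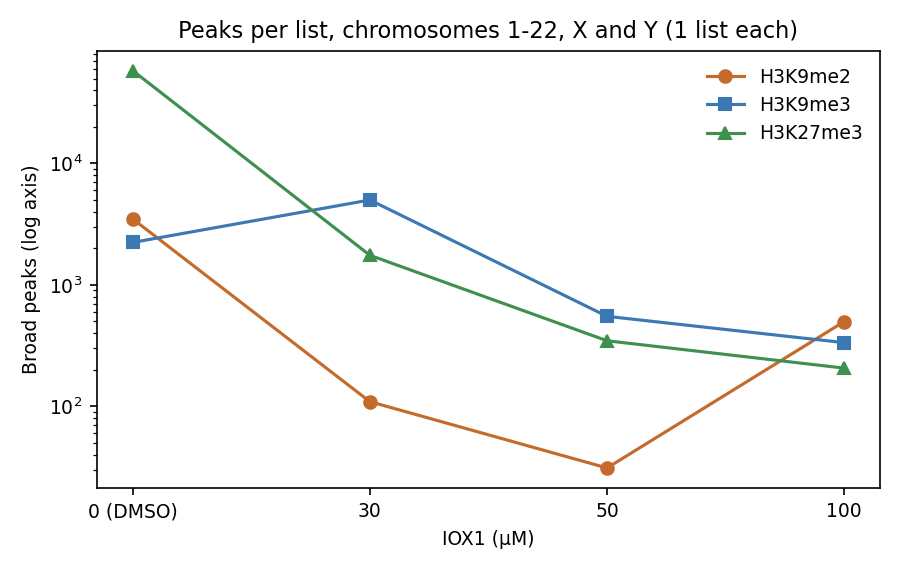
Number of broad peaks per list (log axis) at 0 (DMSO), 30, 50 and 100 µM IOX1 for 3 histone marks, with 1 list per point and no replicates. The H3K27me3 list went from 58131 to 206 peaks, and the H3K9me3 list was longest at 30 µM, with 4999.

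Peaks at 100 µM were set against the DMSO list of the same mark, to see whether they lay in the same regions. They did for 178 of 206 (86.4%, interval 81.0 to 90.8) of H3K27me3, 309 of 334 (92.5%, interval 89.1 to 95.1) of H3K9me3 and 255 of 498 (51.2%, interval 46.7 to 55.7) of H3K9me2. At 30 µM they did for 101 of 109 (92.7%, interval 86.0 to 96.8) of H3K9me2, 1525 of 1750 (87.1%, interval 85.5 to 88.7) of H3K27me3 and 1170 of 4999 (23.4%, interval 22.2 to 24.6) of H3K9me3. At 50 µM they did for 26 of 31 (83.9%, interval 66.3 to 94.5) of H3K9me2, 336 of 346 (97.1%, interval 94.7 to 98.6) of H3K27me3 and 384 of 550 (69.8%, interval 65.8 to 73.6) of H3K9me3. Of the DMSO peaks, 150 of H3K9me3, 45 of H3K27me3 and 0 of H3K9me2 were overlapped in all 3 treated lists. Regions with a peak in at least 8 of the 12 lists, picked after the results were seen, held 8.26%, 80.6% and 29.7% of H3K9me2 peaks at 30, 50 and 100 µM. They held 2.60%, 30.5% and 64.1% of H3K9me3 peaks and 5.43%, 23.1% and 43.7% of H3K27me3 peaks. In DMSO these shares were 6.48%, 5.01% and 0.205% for H3K9me2, H3K9me3 and H3K27me3.

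Among named regions, the widest H3K9me3 peaks in DMSO both lay on chromosome 19, at 37278424 to 37283325 and, over CYKILR, at 36302653 to 36307436, and each had a peak at all 3 doses. The highest H3K27me3 folds in DMSO lay over RGS6 (chromosome 14, 71931945 to 71933069, fold 11.3) and ADAM23 (chromosome 2, 206443273 to 206444318, fold 11.3). RGS6 had a peak at 30 and 50 µM and ADAM23 at 50 and 100 µM. A wide H3K27me3 peak over PRDM12 (chromosome 9, 130659113 to 130665213) was listed at 30 µM, and a peak over SP8 (chromosome 7, 20784233 to 20786085) at all 3 doses. For H3K9me2, a peak over TBC1D5 (chromosome 3, 17402168 to 17402258, fold 6.78) and the widest, over the DUX4-like gene DUX4L3 (chromosome 4, 190087823 to 190089229), were listed again at 100 µM only among the treated H3K9me2 lists. Some of these regions had peaks whatever the mark, as counted after the results were seen. Over the 3 marks, the DUX4L3 region and the first chromosome 19 region each had a peak in 10 of the 12 lists, and the CYKILR region in 8. An H3K27me3 peak at the lower-coordinate end of PGK1, a glycolytic kinase gene, was in DMSO (chromosome X, 78103724 to 78104436, fold 6.87) and in all 3 treated lists. Over the 3 marks, 10 of the 12 lists had a peak there, with folds from 4.70 to 12.05.

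**Figure D4:**
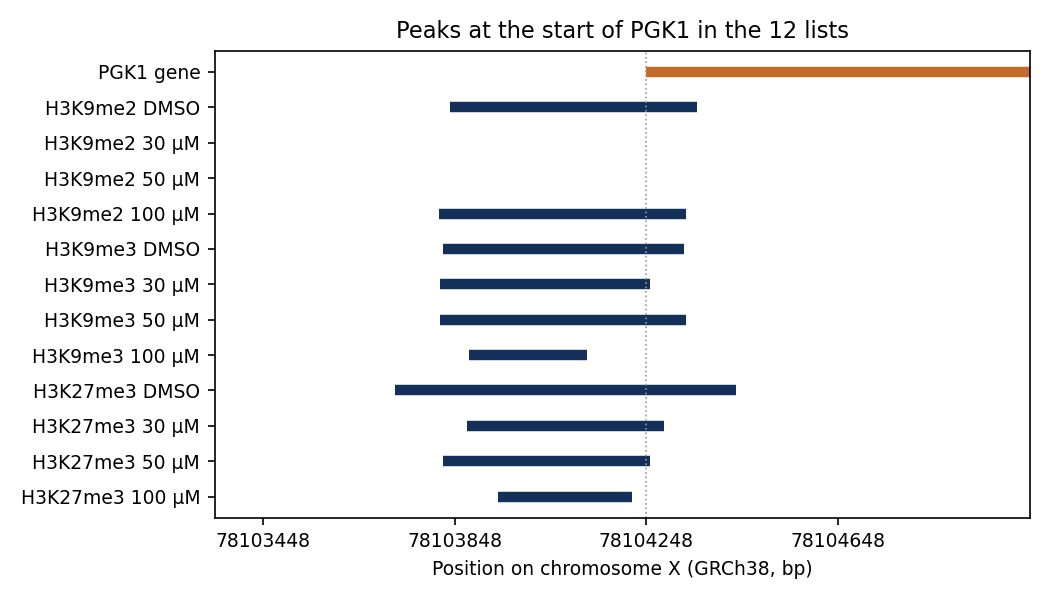
Peaks (dark bars) at the lower-coordinate end of PGK1 (orange bar, first part of the gene; dotted line, its first base) on chromosome X in each of the 12 lists, in bp of GRCh38. A peak is in 10 of the 12 lists, crossing that base or lying just before it.

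The last comparison joined the assays, to ask whether genes under a DMSO peak changed their RNA. The 4948 tested genes with an H3K27me3 peak had median log2 fold changes of 0.05, 0.13 and 0.17 at 30, 50 and 100 µM, against -0.01, -0.04 and -0.14 for other genes. At 100 µM, 2173 of them were higher and 1740 lower. Camera did not call this set (adjusted p = 0.379, 0.180 and 0.195). The 864 genes with an H3K9me2 peak and the 351 with an H3K9me3 peak were not called either (lowest camera adjusted p = 0.464). The H3K9me2 set at 30 µM had a median of 0.03 and a mean of -0.02, which differ in sign. KDM4B had H3K9me2 and H3K27me3 peaks over the gene in DMSO, KDM4C peaks of all 3 marks, and KDM4A and KDM4D none. Any peak over the span or within 1 kb of it counted, so a longer gene had more room for one. Length was not taken into account for these single genes. With peaks of -log10 q of at least 3, camera called the 1752 H3K27me3 genes at 100 µM (adjusted p = 0.0247), while its adjusted p for all H3K27me3 peaks ran from 0.170 to 0.534 over the other camera settings. Genes with an H3K27me3 peak had a median length of 49.1 kb, against 18.4 kb for other genes. Against 10000 random gene sets matched on length and expression, a test chosen after seeing the data, the H3K27me3 median at 100 µM was higher (0.17 against -0.07 to 0.02 for the central 95% of the sets). Its two-sided permutation p was 2.00e-04 at each dose before adjustment, the smallest these sets can give, and 6.00e-04 adjusted. The random sets ignore correlation between genes.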

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

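The tests of H3K9me3 and H3K27me3 alone, of overlap with other marks, of a loss that grows with dose, of mitochondrial protein transcripts and of vector DNA were chosen after the results were seen, as was RNU6-1.

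Some genes changed direction between doses, which stood out because the effects at the doses differ. The test between the doses was also called for each of them. Opposite calls against the same DMSO libraries all but fix that outcome, so it adds no support. Between 50 and 100 µM, 289 genes were lower and then higher than DMSO, and 603 were higher and then lower. Between 30 and 100 µM these were 199 and 313 genes. SPP1 was at -2.21 ± 0.36 at 30 µM and 11.38 ± 0.28 at 100 µM, KLHL4 at -2.76 ± 0.262 and 4.73 ± 0.195, IL7R at -2.59 ± 0.298 and 3.49 ± 0.216, and PNCK at -3.95 ± 0.404 and 2.12 ± 0.273. Outside the sequences analysed, the 12 lists held 3085 peaks on contigs other than chromosomes 1-22, X and Y.

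Peak lists were shorter in all 3 marks at 50 and 100 µM. Weaker detection of the same regions in every mark predicted a high fold percentile of the DMSO peaks still overlapped. For H3K9me2 the median percentile in the DMSO list was 11.1 at 100 µM and 21.2 at 50 µM, against that prediction. Also, 243 of the 498 peaks at 100 µM lay outside that list. Fold may rank detection poorly here, as folds of repeat regions may be low. By -log10 q of at least 3, H3K9me2 at 100 µM had 0.244 of the DMSO number of peaks, against 0.143 for all peaks. That ratio also counts peaks outside the DMSO list, so it does not decide on weaker detection. The percentiles argue against weaker detection in this mark only as far as fold ranks detection. Taken alone, H3K9me3 had percentiles of 76.3 at 50 µM and 79.8 at 100 µM, both in the range that weaker detection predicts, while H3K27me3 had 98.2 at 50 µM, also in that range, and 64.0 at 100 µM, which leaves it open. Regions called whatever the antibody stay open too, since in 3 of 3 marks the peaks at 100 µM overlapped other marks' DMSO lists more often than the DMSO peaks did (63.6% against 3.33% for H3K27me3). A loss of methylation that grows with dose cannot be told apart from these, since 1 of 3 marks had a list that shortened at each step and ChIP depth is unknown.

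The share of mitochondrial ribosomal RNA rose at 50 and 100 µM, with log2 fold changes of 1.36 ± 0.113 and 5.18 ± 0.133 for MT-RNR2 and 1.46 ± 0.146 and 6.20 ± 0.179 for MT-RNR1. More mitochondrial RNA of all kinds is argued against, since MT-RNR2 at 100 µM lay 5.17 above the median of the 13 mitochondrial protein transcripts, whose SD was 0.63. Weaker poly(A) selection cannot be told apart from a change in the cells, since 8 other tested RNAs without poly(A) tails had a median of 1.37 (quartiles 0.20 to 3.09). Of these, 3 were higher and 1 lower. An effect of IOX1 on mitochondrial RNA in the cells stays open and was not tested.

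Peaks lay at the ends of PGK1 in 10 of 12 lists and of RNU6-1, a U6 RNA gene, in 8, whatever the antibody. Open promoters of highly expressed genes are argued against, since 1 of the 500 genes highest in DMSO, PGK1 itself, had a peak near an end in 8 or more lists. DNA of expression vectors, which often carry both promoters, may be a source and cannot be told apart from other causes. 0 lists had a peak in the rest of PGK1, but 0 of 3 other promoters used in vectors had peaks in 8 or more lists. An effect of IOX1 on these peaks was not tested.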

How the results depend on the processing

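Settings without mitochondrial genes, without regions in at least 8 lists, and with random sets matched on length and expression were chosen after seeing the data, as were the tests of other splits. No named gene reversed under any setting run, and no list called in both settings changed direction. Counts were compared by size only, and whether more genes were higher or lower turned in some settings. For 100 against 50 µM, RLE factors gave 5920 higher and 5699 lower, against 5671 and 5940. For 50 µM against DMSO, upper-quartile factors gave 4360 and 4375, against 4600 and 4143. For 50 against 30 µM, leaving out 50 µM replicate 1 gave 2321 and 2479, against 2916 and 2530. For H3K9me3 at 30 µM, with no test, -log10 q of at least 3 took the ratio of peaks to DMSO from 2.24 to 0.844 and that of covered length from 1.69 to 0.768, which turns the direction. Other settings moved 3 of 275 count comparisons: genes lower at 30 µM numbered 2285 with only the 6 libraries compared, those lower by at least 1 numbered 267 with the stricter filter, which tests fewer genes, and calls of gene lists fell to 4 with an estimated correlation. With 1 of the 6 compared libraries left out, genes lower at 30 µM numbered 837 to 925, with fewer samples. With 1 of all 12 libraries left out, those lower at 30 and 50 µM numbered 692 to 1486 and those lower at 30 and 100 µM 617 to 1309. Both overlaps were highest, and above the counts with all libraries, without 100 µM replicate 1, and the cause was not tested; the count lower at 30 µM alone was not recomputed without 50 or 100 µM libraries. Named genes stayed on their side of the threshold in 3713 of 3730 comparisons with other settings and 2411 of 2502 with 1 compared library left out, and list tests in 613 of 630 of the latter.

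Ratios of peaks to the DMSO list moved as follows, and the cause was not tested. With -log10 q of at least 3 they were 0.127, 0.0317 and 0.244 for H3K9me2 at 30, 50 and 100 µM and 0.00264, 0.00215 and 0.00104 for H3K27me3. Covered length ratios were then 0.119 and 0.0215 for H3K9me2 at 30 and 50 µM, 0.177 and 0.0793 for H3K9me3 at 50 and 100 µM, and 0.00106, 7.69e-04 and 4.72e-04 for H3K27me3. With a fold of at least 3, H3K9me2 at 30 µM had 0.00227 of the peaks and 0.00174 of the length. The median fold of that list was 1.91, against 4.11 in the H3K9me2 list of DMSO. With merging, H3K9me2 at 30 µM had 0.0144 of the peaks and 0.100 of the length. H3K9me2 at 100 µM then had 0.292 of the length. H3K9me3 at 100 µM had 0.0908 of the peaks and H3K27me3 at 100 µM 0.00270 of the length. Without regions in at least 8 lists, peaks and length were 0.00184 and 0.00214 for H3K9me2 at 50 µM, 0.0566 and 0.0411 for H3K9me3 at 100 µM and 0.00200 and 8.22e-04 for H3K27me3 at 100 µM, and H3K9me3 at 50 µM had 0.159 of the length. With overlap over at least 0.5 of the peak, the share overlapping the DMSO list was 41.97% for H3K9me2 at 100 µM and 17.2% and 63.3% for H3K9me3 at 30 and 50 µM, and the other 6 shares stayed within their intervals.

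Genes with an H3K27me3 peak became called at 100 µM with -log10 q of at least 3 (camera adjusted p = 0.0247). Against 10000 random sets, which ignore correlation between genes, the medians were higher, with adjusted two-sided permutation p = 0.0231 for H3K9me2 and 0.0231 for H3K9me3 at 30 µM, 0.0166 for H3K9me2 at 50 µM, and 6.00e-04 for H3K27me3 at each dose. Before adjustment the H3K27me3 permutation p was 2.00e-04, the smallest these sets can give. The others did not pass: H3K9me3 at 50 µM (higher, 0.400), H3K9me2 at 100 µM (higher, 0.0908) and H3K9me3 at 100 µM (lower, 0.424).

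Whether the replicate numbers pair the libraries is unsettled. Only 5 of 18 same-number pairs correlated over 0.1 (range -0.39 to 0.31). Yet 8 of 12 libraries correlated best with their own number, a hint of pairing from the data only. With the replicate block, genes higher and lower were 1821 and 1216 at 30 µM, 4479 and 4036 at 50 µM and 6257 and 6597 at 100 µM. It ended the call of KDM4D at 50 µM and of no other named gene, and no list call with the preset correlation. Of the 4 list calls that held with an estimated correlation, the block with an estimated correlation kept interferon-stimulated genes at 50 µM (camera adjusted p = 0.0472) and did not keep inflammatory genes at 50 and 100 µM or G2/M genes at 100 µM (camera adjusted p = 0.0659, 0.0659 and 0.0659).

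For each pair of groups, 10 splits of 6 libraries are too few for a share under 0.05. The real split called 3350, 8743, 12971, 5446, 11611 and 12586 genes for 30, 50 and 100 µM against DMSO, 50 against 30, 100 against 50 and 100 against 30 µM, and the highest other split called 0. For the joint test, 1 of 60 regroupings, the real one, called as many as 14124 genes, and the highest other called 12341. That share is under 0.05, which argues against a grouping by chance for this count. It does not exclude it, as only 60 regroupings were tried. In simulations at these depths edgeR recovered 22.4%, 19.4% and 22.4% of log2 changes of 0.5 at 30, 50 and 100 µM. Far fewer genes were changed in them than were called in the real comparisons, so these rates need not hold there. Depth was not separated from the number of libraries or their spread.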

Other observations

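The regions with a peak in at least 8 lists were examined only after the results were seen. The remaining lists are given first. Of 18 other JmjC demethylase genes, 4 were higher and 1 lower at 30 µM, 6 were higher and 4 lower at 50 µM, and 9 were higher and 5 lower at 100 µM (4 and 1, 6 and 5, and 9 and 5 adjusted over the list alone, camera adjusted p = 0.0803, 0.673 and 0.0870), with KDM3A at 4.08 ± 0.109 and KDM7A at 4.72 ± 0.172 at 100 µM. Of 33 other 2-oxoglutarate oxygenase genes, 3 were higher and 6 lower at 30 µM, 9 were higher and 7 lower at 50 µM, and 16 were higher and 15 lower at 100 µM (5 and 6, 9 and 7, and 16 and 15 adjusted over the list alone, camera adjusted p = 0.558, 0.673 and 0.558), with the prolyl hydroxylase genes EGLN3 at 6.60 ± 0.255 and P4HA2 at 4.32 ± 0.121 and the demethylase gene FTO at -2.06 ± 0.086 at 100 µM. Of 31 Polycomb genes, 7 were higher and 0 lower at 30 µM, 12 were higher and 1 lower at 50 µM, and 15 were higher and 8 lower at 100 µM (9 and 0, 12 and 1, and 15 and 8 adjusted over the list alone, camera adjusted p = 0.113, 0.0748 and 0.241), with PHC2 at 3.37 ± 0.112 at 100 µM. Of 6 PAF1 complex genes, 0 were higher and 0 lower at 30 µM, 0 were higher and 3 lower at 50 µM, and 2 were higher and 3 lower at 100 µM (0 and 0, 0 and 3, and 2 and 3 adjusted over the list alone, camera adjusted p = 0.526, 0.0667 and 0.673), with LEO1 at -0.74 ± 0.094 at 50 µM. Of 4 KDM4 genes, 1 was higher and 0 lower at 30 µM, 2 were higher and 0 lower at 50 µM, and 2 were higher and 1 lower at 100 µM (1 and 0, 2 and 0, and 2 and 1 adjusted over the list alone, camera adjusted p = 0.615, 0.278 and 0.476). 

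Of 23 iron-handling genes, 5 were higher and 2 lower at 30 µM, 6 were higher and 7 lower at 50 µM, and 9 were higher and 10 lower at 100 µM (5 and 2, 6 and 7, and 9 and 10 adjusted over the list alone, camera adjusted p = 0.529, 0.998 and 0.742), with the ferritin gene FTH1 at 5.22 ± 0.185 at 100 µM. Of 24 cholesterol biosynthesis genes, 1 was higher and 0 lower at 30 µM, 2 were higher and 11 lower at 50 µM, and 7 were higher and 13 lower at 100 µM (1 and 0, 2 and 11, and 7 and 13 adjusted over the list alone, camera adjusted p = 0.673, 0.0762 and 0.274), with SQLE at 3.36 ± 0.138 and FDPS at -3.20 ± 0.129 at 100 µM. Of 22 genes of the KMT2A-fusion programme, 2 were higher and 3 lower at 30 µM, 5 were higher and 7 lower at 50 µM, and 7 were higher and 11 lower at 100 µM (2 and 4, 5 and 7, and 7 and 11 adjusted over the list alone, camera adjusted p = 0.218, 0.417 and 0.277), with MYB at -4.64 ± 0.11 at 100 µM. Of 9 neutrophil granule genes, 2 were higher and 3 lower at 30 µM, 3 were higher and 3 lower at 50 µM, and 2 were higher and 7 lower at 100 µM (4 and 3, 4 and 3, and 2 and 7 adjusted over the list alone, camera adjusted p = 0.583, 0.837 and 0.0565), with the myeloperoxidase gene MPO at -1.66 ± 0.102 and MMP9 at 6.45 ± 0.178 at 100 µM. Without 100 µM replicate 2 the neutrophil list was called at 100 µM (camera adjusted p = 0.0296).

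Of 14 genes of a leukaemia stem cell score, 1 was higher and 2 lower (1 and 2 adjusted over the list alone) at 30 µM, with NYNRIN at -0.94 ± 0.115 (camera adjusted p = 0.0108, and adjusted p = 0.188 with an estimated correlation). That call was lost without 30 µM replicate 3 (adjusted p = 0.0608). Of 13 mitochondrially encoded protein genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone) at 30 µM (camera adjusted p = 0.0147, and adjusted p = 0.632 with an estimated correlation). Without DMSO replicate 3 or 30 µM replicate 3 that call was lost (adjusted p = 0.0973 and 0.105). Of 421 ZNF-named genes, 54 were higher and 21 lower (45 and 19 adjusted over the list alone) at 30 µM, with ZNF467 at 0.85 ± 0.109 (camera adjusted p = 0.0286, and adjusted p = 0.635 with an estimated correlation). Without DMSO replicate 1 or 30 µM replicate 3 that call was lost (adjusted p = 0.0604 and 0.1102). Of 40 nuclear oxidative phosphorylation genes, 1 was higher and 12 lower (0 and 10 adjusted over the list alone) at 50 µM (camera adjusted p = 0.00945, and adjusted p = 0.665 with an estimated correlation), a call lost without 50 µM replicate 3 (adjusted p = 0.0553).

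Lists called at other doses were not called at the following. Of 38 DNA replication and G1/S genes, 7 were higher and 1 lower (7 and 1 adjusted over the list alone) at 30 µM, and 15 were higher and 7 lower (15 and 7 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.167 and 0.167. Of 26 homologous recombination and Fanconi genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone) at 30 µM, and 6 were higher and 4 lower (6 and 3 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.660 and 0.947. Of 18 H3K9 methyltransferases and readers, 0 were higher and 1 lower (0 and 1 adjusted over the list alone) at 30 µM, and 1 was higher and 7 lower (1 and 7 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.467 and 0.0793. Of 20 glycolysis genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone) at 30 µM, and 10 were higher and 4 lower (11 and 5 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.5003 and 0.0983. Of 21 ER chaperone genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone) at 30 µM, and 7 were higher and 1 lower (6 and 1 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.0901 and 0.287. Of 18 BCL2 family genes, 4 were higher and 0 lower (4 and 0 adjusted over the list alone) at 30 µM, with camera adjusted p = 0.274. Of 54 cytosolic ribosomal protein genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone) at 30 µM, and 8 were higher and 0 lower (2 and 0 adjusted over the list alone) at 50 µM, with camera adjusted p = 0.673 and 0.277. Of 40 nuclear oxidative phosphorylation genes, 1 was higher and 0 lower (0 and 0 adjusted over the list alone) at 30 µM, with camera adjusted p = 0.837. Of 23 p53 targets, 13 were higher and 6 lower (13 and 6 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.167. Of 36 genes of the amino acid stress response, 18 were higher and 7 lower (18 and 9 adjusted over the list alone) at 50 µM, and 16 were higher and 13 lower (16 and 13 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.0748 and 0.673. Of 9 metallothioneins and metal response genes, 2 were higher and 6 lower (2 and 6 adjusted over the list alone) at 50 µM, and 3 were higher and 4 lower (3 and 4 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.0614 and 0.770. Of 14 stem cell score genes, 4 were higher and 7 lower (4 and 8 adjusted over the list alone) at 50 µM, and 5 were higher and 8 lower (5 and 8 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.488 and 0.5003. Of 13 mitochondrially encoded protein genes, 5 were higher and 0 lower (5 and 0 adjusted over the list alone) at 50 µM, and 4 were higher and 0 lower (4 and 0 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.0803 and 0.525. Of 421 ZNF-named genes, 128 were higher and 66 lower (126 and 62 adjusted over the list alone) at 50 µM, and 135 were higher and 166 lower (135 and 165 adjusted over the list alone) at 100 µM, with camera adjusted p = 0.167 and 0.648. Leaving out 1 library gave calls for ER chaperones at 30 µM (30 µM replicate 1, camera adjusted p = 0.0462) and at 50 µM for glycolysis and cytosolic ribosomal proteins (50 µM replicate 3, camera adjusted p = 0.0451 and 0.0253), the amino acid stress response and cholesterol biosynthesis (DMSO replicate 3, camera adjusted p = 0.0203 and 0.0203) and mitochondrially encoded proteins (DMSO replicate 1, camera adjusted p = 0.0295).

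Markers of other cell types were counted too. Of 4 B cell markers, 1 was higher and 0 lower at 30 µM, 1 was higher and 0 lower at 50 µM, and 0 were higher and 3 lower at 100 µM (1 and 0, 1 and 0, and 0 and 3 adjusted over the list alone, camera adjusted p = 0.772, 0.673 and 0.106). Of 3 megakaryocyte markers, 0 were higher and 0 lower at 30 µM, 1 was higher and 1 lower at 50 µM, and 0 were higher and 2 lower at 100 µM (0 and 0, 1 and 1, and 0 and 2 adjusted over the list alone, camera adjusted p = 0.712, 0.910 and 0.301). Of 4 fibroblast and epithelial markers, 0 were higher and 1 lower at 30 µM, 2 were higher and 1 lower at 50 µM, and 2 were higher and 1 lower at 100 µM (0 and 1, 2 and 1, and 2 and 1 adjusted over the list alone, camera adjusted p = 0.120, 0.717 and 0.645). T cell and erythroid markers had 2 and 1 tested members, too few for a set test: TRAC was at 3.39 ± 0.248 and CD8A at 1.98 ± 0.223 at 100 µM, and KLF1 had 118 counts in DMSO and 0 at 100 µM, at least 25.5-fold lower. Median, mean and test differed in sign in some lists that camera did not call. For the leukaemia stem cell score at 100 µM the median was -0.78, the mean 0.71 and the test direction down, with EMP1 at 11.02 ± 0.256 and ADGRG1 at 8.22 ± 0.203 among its members. The same held in sign at 50 µM. For neutrophil genes at 50 µM the median was 0.26 and the mean -0.05. Signs also differed for 2-oxoglutarate oxygenases, H3K9 genes, glycolysis, oxidative phosphorylation, B cell and neutrophil lists at 30 µM, iron handling and megakaryocyte lists at 50 µM, and metallothioneins at 100 µM.

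Regions with a peak in at least 8 of the 12 lists numbered 94. By gene name, 28 of these were DUX4-like, 15 ribosomal DNA, 3 REXO1L copies, 1 the DXZ4 repeat and 47 others, and 19 lay on chromosome 19.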
